A study of Shewanella oneidensis MR-1 with 9 samples.

How the data were processed

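RNA was sequenced from 9 samples of Shewanella oneidensis MR-1, 3 biological replicates each of WT, SCFP1 and SPK2DK. Per the labels' protocols, bacteria were grown overnight in LB medium at 30 °C with IPTG when needed, and stranded total RNA libraries were made after rRNA depletion. The deposited counts are whole numbers per gene, 1 table per library, with no normalization seen in the values. The aligner, the counting tool, its use of strand and the genome build are not given in the sources used here, so genes that overlap or lie antisense to each other are uncertain. The deposited FPKM values equal the count scaled by gene length and library total for 97.8% of genes with counts (relative tolerance 0.001), so they carry no further normalization. Every FPKM column was matched to a library by its name.

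The tables hold 4407 genes, of which 4403 matched the RefSeq gene table of assembly ASM14616v2 by locus tag and 4 did not. A symbol was found for 1231 genes, and the other 3176 are given by locus tag. Because the build of the files is not given, this table was used only for names, gene types, lengths, replicons and which genes neighbour each other. It gives no product names, so the rule below was applied to genes with a symbol.

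Rows that share reads were looked for in the values after the data were seen. There were 25 families of rows of equal length whose counts differed by at most 1.1-fold in every library (mean count at least 50), with 129 rows, the largest family having 40. These rows took 9.52% to 20.0% of a library's counts, which points to reads counted at every copy. They are uncertain, none is named in the text, and an alternative kept 1 row per family. Several families had the same length of 1203 bases, so rows that share reads may remain in that alternative.

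Differential expression was tested on the counts with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, robust quasi-likelihood fit, Benjamini-Hochberg adjustment, threshold 0.05). All 9 libraries entered 1 fit with a mean per strain, which kept 4393 genes, and the 3 pairwise contrasts were tested. CPM use the TMM-scaled library size, and standard errors (SE) are the unshrunken log2 fold change divided by the square root of the F statistic. The SE and adjusted p values take 1 spread per gene for all strains, although replicates of WT were less alike than those of the other strains. Before the data were examined 31 gene lists were fixed, of which 29 had members and 27 had at least 3 tested members. As product names were missing, members were matched only by symbol or by a listed locus tag. Counts of list genes, also where all changed, therefore refer to the members matched and not to whole pathways. The lists were tested with camera in limma 3.58.1 on voom values, with the inter-gene correlation preset at 0.01 and also estimated. Figures were drawn with matplotlib 3.10.9, and tables were joined with pandas 2.3.3 in Python 3.11.15.

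The genes named were chosen by a rule set before the data were examined. For each comparison it took, among genes at an adjusted p below 0.05 whose strains did not overlap and that had a symbol, the 8 largest rises and falls (5 for SPK2DK against SCFP1). It also took up to 3 members with the largest changes in each list described, the members of the electron transfer list, the lactate utilisation genes SO_1518 to SO_1522, atpA and atpD whatever their result, and 4 genes per direction of the overlap. Genes outside this rule are said to be chosen after their values were seen.

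Depth ranged from 4892281 to 6031900 counts per library, and 3 counts in a library correspond to 0.497 to 0.613 CPM. The edgeR step was tested on simulated data with 200 changed genes per comparison. For SCFP1 against WT it recovered 59.7% of genes changed 1.5-fold, 95.5% of those changed 2-fold and 100.0% of those changed 4-fold, with 4386 genes tested and 3.08% of calls false. For SPK2DK against WT these were 55.2%, 97.0% and 100.0% (4388 genes, 5.53% false), and for SPK2DK against SCFP1 62.7%, 86.6% and 100.0% (4384 genes, 5.10% false). The 200 genes held as many rises as falls, and a small planted list rose besides them. In the data 73.7% to 80.6% of genes were called, so the simulated shares of false calls do not carry over to the data.

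Alternatives were median-of-ratios factors, library totals, no low-count filter, DESeq2 1.42.0, only the strains compared, the replicate number as a block, rRNA and tRNA rows left out, the 10 most abundant genes left out, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and each library left out in turn. Leaving out ssrA and rnpB, removing a gene length trend and keeping 1 row per family were added after seeing the data.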

Results

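Gene expression was measured by RNA sequencing in Shewanella oneidensis MR-1, a bacterium that respires a wide range of electron acceptors, some of them outside the cell. The series compared 3 strains with 3 biological replicates each: the wild type (WT), SCFP1, which the labels describe as energetically decreased, and SPK2DK, described as energetically enhanced. The labels do not name the introduced genes, so no target gene could be checked, and they do not say which cultures received the inducer IPTG. Total counts per library were 4941704, 4892281 and 5304768 in WT, 5953785, 5850845 and 6031900 in SCFP1, and 5449108, 5598838 and 5514273 in SPK2DK.

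The libraries differed in how much of their count fell on a few transcripts. The tmRNA gene ssrA, whose product rescues stalled ribosomes, took 18.9% ± 4.05 (SD, n = 3) of the counts in WT, 2.66% ± 0.285 (SD, n = 3) in SCFP1 and 6.42% ± 0.131 (SD, n = 3) in SPK2DK. The RNase P RNA gene rnpB took 9.48% ± 2.02 (SD, n = 3), 1.74% ± 0.121 (SD, n = 3) and 6.84% ± 1.5 (SD, n = 3). Both genes were chosen after their values were seen. In single WT libraries the ssrA share ranged from 15.1% (95% Wilson interval 15.1 to 15.2, replicate 2) to 23.2% (23.1 to 23.2, replicate 3), and such intervals cover counting error only. WT replicates were the least alike, with a chi-square per degree of freedom of 102 between replicates 2 and 3, against 1.46 for SCFP1 replicates 1 and 2. No pair agreed within sampling noise, so none was merged as a library deposited more than once. This comparison does not show that the libraries are independent, which rests on the design text of the series, where they are called biological replicates.

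In SCFP1 against WT, all 16 listed genes of hydrogen and formate metabolism and 12 of 15 NADH dehydrogenase genes were lower. Higher were 11 of 15 listed DNA repair genes and all 9 listed phosphate genes, while 2 NADH dehydrogenase genes rose and 2 repair genes fell. Camera called these lists with its preset correlation and 0 of them with an estimated one (adjusted p = 0.423 to adjusted p = 0.910 with an estimated correlation). The ribosome modulation factor gene rmf fell from 1367 ± 444 CPM (SD, n = 3) in WT to 7.87 ± 0.715 CPM (SD, n = 3) in SCFP1, a log2 fold change of -7.44 ± 0.26 (SE). The DNA repair gene recN rose from 126 ± 3.22 CPM (SD, n = 3) to 2349 ± 97.8 CPM (SD, n = 3), a log2 fold change of 4.23 ± 0.10 (SE). The decaheme cytochrome gene mtrC, of the pathway that carries electrons across the outer membrane, fell from 244 ± 64.9 CPM (SD, n = 3) to 63.9 ± 2.28 CPM (SD, n = 3). Of 4393 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1755 were higher and 1787 lower at an adjusted p below 0.05, and 956 and 1074 of them by at least 2-fold. The 3 values of one strain all lay above those of the other for 82.0% of genes, against 10% by chance.

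Among genes with a symbol, the other large rises in SCFP1 were those of nadS (SO_RS22440) with a log2 fold change of 5.26 ± 0.18 (SE) and nadS (SO_RS22830) with 4.90 ± 0.30, both on the megaplasmid. They were followed by xseB, a subunit of exonuclease VII (3.78 ± 0.20), rnt, encoding ribonuclease T (3.75 ± 0.17), dsbB (3.63 ± 0.12), yidD (3.53 ± 0.13) and rnpA, the protein part of RNase P (3.27 ± 0.18). The other large falls were in exaC (-5.38 ± 0.13), the alanine dehydrogenase gene ald (-5.28 ± 0.19), cspD (-5.16 ± 0.22), the cytochrome bd oxidase subunit gene cydX (-4.92 ± 0.27), hppD (-4.78 ± 0.20) and fhuF (-4.73 ± 0.19). Counts were low for nadS (SO_RS22830) in WT (7, 6 and 9) and for cydX in SCFP1 (7, 8 and 9). The sizes of these folds are therefore less certain. The 5S rRNA gene rrf (SO_RS20855) also met the naming rule, with 14, 16 and 10 counts in WT and 0, 0 and 1 in SCFP1. It shares sequence with other rRNA copies, so its value is uncertain and no fold is given.

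All 16 genes of hydrogenases and formate dehydrogenases fell in SCFP1, also 16 adjusted over the list alone, with a median log2 fold change of -2.32. Examples are hypE (-3.33 ± 0.15, SE), fdhE (-2.93 ± 0.14) and hydF (-2.83 ± 0.25). The list passed limma's camera test (adjusted p = 1.9e-05) with the preset correlation and did not with an estimated one (adjusted p = 0.435 with an estimated correlation). Of 15 NADH dehydrogenase genes, 12 fell and 2 rose, the same counts adjusted over the list alone, among them nqrE (SO_RS04240) (-2.54 ± 0.21), nuoN (-2.46 ± 0.18) and nuoM (-2.41 ± 0.18). Its camera test gave adjusted p = 0.0179, and adjusted p = 0.910 with an estimated correlation. Of 15 genes of the SOS response and DNA repair, 11 rose and 2 fell, or 11 and 3 adjusted over the list alone, including the recombinase gene recA (3.19 ± 0.13) and the SOS repressor gene lexA (2.92 ± 0.13). The list test gave adjusted p = 0.0179, and adjusted p = 0.435 with an estimated correlation.

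All 9 phosphate and polyphosphate genes rose in SCFP1, also 9 adjusted over the list alone, with a median of 1.37 and with phoB (1.90 ± 0.13, SE) and pstB (SO_RS19885) (1.75 ± 0.14) as examples. The members as a set had adjusted p = 0.0179, and adjusted p = 0.423 with an estimated correlation. Of 20 aminoacyl-tRNA synthetase genes, 15 rose and 2 fell, the same counts adjusted over the list alone, led by pheS (2.14 ± 0.14), aspS (1.98 ± 0.11) and hisS (1.85 ± 0.09). For this list camera gave adjusted p = 0.0179 and adjusted p = 0.910 with an estimated correlation. Of 32 genes of cell wall and lipopolysaccharide synthesis, 19 rose and 5 fell, the same counts adjusted over the list alone, led by lptD (2.64 ± 0.14), lptA (1.67 ± 0.11) and mraZ (1.56 ± 0.12). Together these genes had adjusted p = 0.0393, and adjusted p = 0.435 with an estimated correlation. The call was also lost with DESeq2 statistics, with only the 2 strains compared and without SCFP1 replicate 3 (median 0.55, camera adjusted p = 0.0579, with 0.0188 to 0.435 over the alternatives).

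Of the 10 genes of the extracellular electron transfer list, 8 fell and 1 rose in SCFP1, the same counts adjusted over the list alone, and the list itself did not pass camera (adjusted p = 0.0523). It passed with 10 alternatives, of which limma on log2(FPKM + 1) with and without its filter was the same fit. Among the 10 were library totals, the replicate block, and fits without WT replicate 2, WT replicate 3 or SCFP1 replicate 1 (camera adjusted p = 0.0280, 0.0452 and 0.0419). Its camera adjusted p ranged from 0.0208 to 0.764 over the alternatives. Lower members were SO_1776 (-2.10 ± 0.16, SE), mtrC (-1.93 ± 0.17), mtrA (-1.84 ± 0.09), cymA (-1.75 ± 0.19), omcA (-1.07 ± 0.13), cctA (-1.03 ± 0.16), mtrF (-0.92 ± 0.22) and fccA (-0.85 ± 0.11), while SO_1782 rose (0.64 ± 0.14) and SO_1781 had a log2 fold change of 0.12 ± 0.12. The genes SO_1518 to SO_1522 of the lactate list fell with log2 fold changes of -3.21 ± 0.17, -2.46 ± 0.13, -0.62 ± 0.08, -0.87 ± 0.09 and -1.56 ± 0.12. Of 7 ATP synthase genes, 6 fell, also 6 adjusted over the list alone, among them atpA (-1.31 ± 0.16) and atpD (-1.14 ± 0.18), and the list did not pass camera (adjusted p = 0.0713). It passed with library totals, with limma on FPKM and without WT replicate 2 (adjusted p = 0.0328), with 0.0209 to 0.949 over the alternatives. Of 54 ribosomal protein genes, 32 rose and 6 fell, or 29 and 6 adjusted over the list alone, and the list did not pass camera (adjusted p = 0.0523). It passed with library totals, the replicate block, the 10 most abundant genes left out, limma on FPKM, the length trend removed, ssrA and rnpB left out, without SCFP1 replicate 1 (adjusted p = 0.0419) and without WT replicate 3 (adjusted p = 0.000402), with 0.000402 to 0.949 over the alternatives. Of 11 stationary-phase genes, 5 fell and 3 rose, the same counts adjusted over the list alone, and the list did not pass camera (adjusted p = 0.814).

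Camera called 6 of 27 lists in this comparison, 4 higher and 2 lower, and 0 with an estimated correlation, where 1 had an unadjusted p below 0.05. Fry, which tests whether members move 1 way without comparing them with other genes, called 18. In fits to these 6 libraries alone camera called 5 lists for the strains and up to 13 for splits that mixed them, which still hold part of the strain difference and so give no reference without one.

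In SPK2DK against WT, all 11 listed genes of the tricarboxylic acid and glyoxylate cycles and 7 of 10 of extracellular electron transfer were higher. So were 44 of 54 ribosomal protein genes and 17 of 18 heat shock genes, while 1 electron transfer gene and 2 ribosomal protein genes fell. These lists passed camera with its preset correlation, and 0 of them with an estimated one (adjusted p = 0.319 to adjusted p = 0.504 with an estimated correlation). The outer membrane protein gene ompW rose from 58.8 ± 14.1 CPM (SD, n = 3) to 2418 ± 39.5 CPM (SD, n = 3), a log2 fold change of 5.37 ± 0.17 (SE). The gene sucC, encoding a subunit of succinyl-CoA synthetase, rose from 173 ± 26.9 CPM (SD, n = 3) to 2760 ± 136 CPM (SD, n = 3), and mtrC rose to 1136 ± 49.0 CPM (SD, n = 3). The phosphate transporter gene pstC fell from 73.9 ± 19.99 CPM (SD, n = 3) to 13.0 ± 2.17 CPM (SD, n = 3), a log2 fold change of -2.5 ± 0.21 (SE). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1545 genes were higher and 1694 lower, and 705 and 546 of them by at least 2-fold. The strains did not overlap for 73.9% of genes, against 10% by chance.

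This split depended on the scaling. Of the genes called, 47.7% were higher with TMM factors and 26.3% with library totals only (938 higher and 2622 lower), and the median log2 fold change of all genes moved from -0.08 to -0.57. By at least 2-fold, 358 were higher and 1432 lower with library totals, and 642 and 650 with the 10 most abundant genes left out. Changes in SPK2DK are therefore given relative to a typical gene, as TMM scales them.

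Of the genes with a symbol, other large rises in SPK2DK were nadS (SO_RS22440) (4.10 ± 0.17, SE), sucD (3.85 ± 0.11), the ribosome hibernation factor genes hpf (SO_RS15870) (3.84 ± 0.20) and hpf (SO_RS15955) (3.57 ± 0.18), the phosphoenolpyruvate synthase gene ppsA (3.66 ± 0.15) and sucA (3.66 ± 0.16). Other large falls were erpA (-2.51 ± 0.21), the flagellar genes fliE (-2.48 ± 0.24), flgF (-2.47 ± 0.15), flgJ (-1.97 ± 0.16) and flgA (-1.93 ± 0.20), and pstA (SO_RS19890) (-1.91 ± 0.19). Of 34 flagellum genes 18 fell and 9 rose, the same counts adjusted over the list alone, and the list passed camera only without WT replicate 2 (adjusted p = 0.159 with all libraries, 0.0262 without that one and 0.0262 to 0.705 over the alternatives). Of 9 phosphate genes 6 fell and 1 rose, the same counts adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0783). The 5S rRNA gene rrf (SO_RS19495) met the rule with 17, 15 and 10 counts in WT and 3, 2 and 3 in SPK2DK, and is uncertain for the same reason as its copy above.

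All 11 genes of the tricarboxylic acid and glyoxylate cycles rose in SPK2DK, also 11 adjusted over the list alone, with a median log2 fold change of 1.84 with TMM factors and 1.34 with library totals. Camera gave adjusted p = 3.8e-06, and adjusted p = 0.363 with an estimated correlation. All 20 aminoacyl-tRNA synthetase genes rose, also 20 adjusted over the list alone, led by aspS (3.06 ± 0.12, SE), glyS (2.5 ± 0.09) and pheS (2.18 ± 0.14). Its camera test gave adjusted p = 3.3e-07 and adjusted p = 0.319 with an estimated correlation. Of 54 ribosomal protein genes, 44 rose and 2 fell, or 44 and 3 adjusted over the list alone, led by rpmC (1.84 ± 0.16), rplV (1.84 ± 0.19) and rplP (1.83 ± 0.18). The list test gave adjusted p = 1.4e-06 and adjusted p = 0.504 with an estimated correlation. Of 18 heat shock genes, 17 rose, also 17 adjusted over the list alone, including the chaperone genes groL (3.09 ± 0.13), dnaK (2.87 ± 0.18) and htpG (2.33 ± 0.11). The members as a set had adjusted p = 5.9e-06 and adjusted p = 0.319 with an estimated correlation.

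Of the 10 extracellular electron transfer genes, 7 rose and 1 fell in SPK2DK, the same counts adjusted over the list alone. The rises were in omcA (2.85 ± 0.13, SE), cymA (2.69 ± 0.18), SO_1776 (2.23 ± 0.16), mtrC (2.22 ± 0.17), mtrA (2.03 ± 0.09), cctA (1.63 ± 0.16) and fccA (1.42 ± 0.11). The fall was in mtrF (-0.80 ± 0.23), while SO_1781 (0.04 ± 0.12) and SO_1782 (-0.15 ± 0.15) did not pass. With library totals SO_1781 (-0.47) and SO_1782 (-0.66) were called lower. For this list camera gave adjusted p = 0.00817, and adjusted p = 0.319 with an estimated correlation. Of 6 cytochrome c maturation genes, 5 rose, also 5 adjusted over the list alone, led by ccmA (1.81 ± 0.14). Together these genes had adjusted p = 0.0196 and adjusted p = 0.425 with an estimated correlation, and the call was also lost with DESeq2 statistics. All 7 ATP synthase genes rose, also 7 adjusted over the list alone, among them atpF (1.25 ± 0.15), atpA (1.06 ± 0.16) and atpD (0.67 ± 0.17). Camera gave adjusted p = 0.0196 and adjusted p = 0.489 with an estimated correlation, and DESeq2 statistics did not call it either. With library totals 4 of the 7 rose, and atpD, at 0.20, did not pass (edgeR adjusted p = 0.158, with 6.2e-05 to 0.158 over the alternatives).

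Of 17 genes of lactate, pyruvate and acetate metabolism, 13 rose and 3 fell in SPK2DK, the same counts adjusted over the list alone, led by ppsA, the acetyl-CoA synthetase gene acs (2.02 ± 0.11, SE) and ppsR (1.5 ± 0.20). Its camera test gave adjusted p = 0.00817, and adjusted p = 0.319 with an estimated correlation. Within it, SO_1521 rose (1.5 ± 0.09), SO_1518 fell (-0.51 ± 0.15) and SO_1519 did not pass (-0.11 ± 0.12), but was called lower with library totals (-0.62) and without WT replicate 3 (-0.22). SO_1520 (0.47 ± 0.08) and SO_1522 (0.35 ± 0.12) rose with TMM factors and turned negative without a call with library totals (-0.032 and -0.17). The call of SO_1522 was also lost with only the 2 strains compared or the 10 most abundant genes left out. Without SPK2DK replicate 3 it was lost too (log2 fold change 0.33, edgeR adjusted p = 0.0587), and its adjusted p ranged from 0.00302 to 0.515 over the alternatives.

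Of 15 genes of sulfate assimilation and cysteine synthesis, 12 rose in SPK2DK, also 12 adjusted over the list alone, led by cysK (3.16 ± 0.17, SE), cysI (2.49 ± 0.13) and cysP (2.38 ± 0.14). For this list camera gave adjusted p = 0.00087 and adjusted p = 0.319 with an estimated correlation. Of 13 genes of branched-chain amino acid and fatty acid degradation, 10 rose and 2 fell, the same counts adjusted over the list alone, led by mmsB (2.69 ± 0.12), prpF (2.23 ± 0.14) and gcvP (2.12 ± 0.09). Its camera test gave adjusted p = 0.00074 and adjusted p = 0.319 with an estimated correlation. The last of these, gcvP, encodes a subunit of the glycine cleavage system. Of 23 genes of purine and pyrimidine synthesis, 18 rose and 4 fell, the same counts adjusted over the list alone, led by nrdB (2.58 ± 0.11), carA (2.54 ± 0.12) and purN (2.23 ± 0.10). The list test gave adjusted p = 0.00212 and adjusted p = 0.319 with an estimated correlation. The median log2 fold change of this list was 0.60, and 0.091 at the lowest over the alternatives. Leaving out single libraries lowered it only to 0.57.

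Of 11 genes of stationary phase and ribosome hibernation, 6 rose and 1 fell in SPK2DK, the same counts adjusted over the list alone, led by hpf (SO_RS15870), hpf (SO_RS15955) and uspE (2.84 ± 0.17, SE), and the median of 0.44 turned to -0.036 with library totals and was 0.25 without WT replicate 2. The list test gave adjusted p = 0.0371, and adjusted p = 0.489 with an estimated correlation. Of 20 anaerobic reductase genes, 14 fell and 3 rose, the same counts adjusted over the list alone, led by nrfD (SO_RS02315) (-1.35 ± 0.29), nrfE (-1.34 ± 0.27) and phsA (-1.22 ± 0.28). The members as a set had adjusted p = 0.0404 and adjusted p = 0.504 with an estimated correlation. The call was also lost with library totals, DESeq2 statistics, limma on FPKM and without WT replicate 2 (median -0.62, camera adjusted p = 0.0555, with 0.0129 to 0.504 over the alternatives). The fall was not particular to SPK2DK. In SCFP1 against WT 12 of the 20 fell and 4 rose, with a median of -1.70 against -0.89 in SPK2DK. There the list did not pass camera (adjusted p = 0.120). In SPK2DK against WT camera called 13 of 27 lists, 12 higher and 1 lower, and 0 with an estimated correlation, where 1 had an unadjusted p below 0.05. Fry, which tests whether members move 1 way without comparing them with other genes, called 24. In fits to these 6 libraries alone camera called 13 lists for the strains and up to 17 for splits that mixed them.

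**Figure D1:**
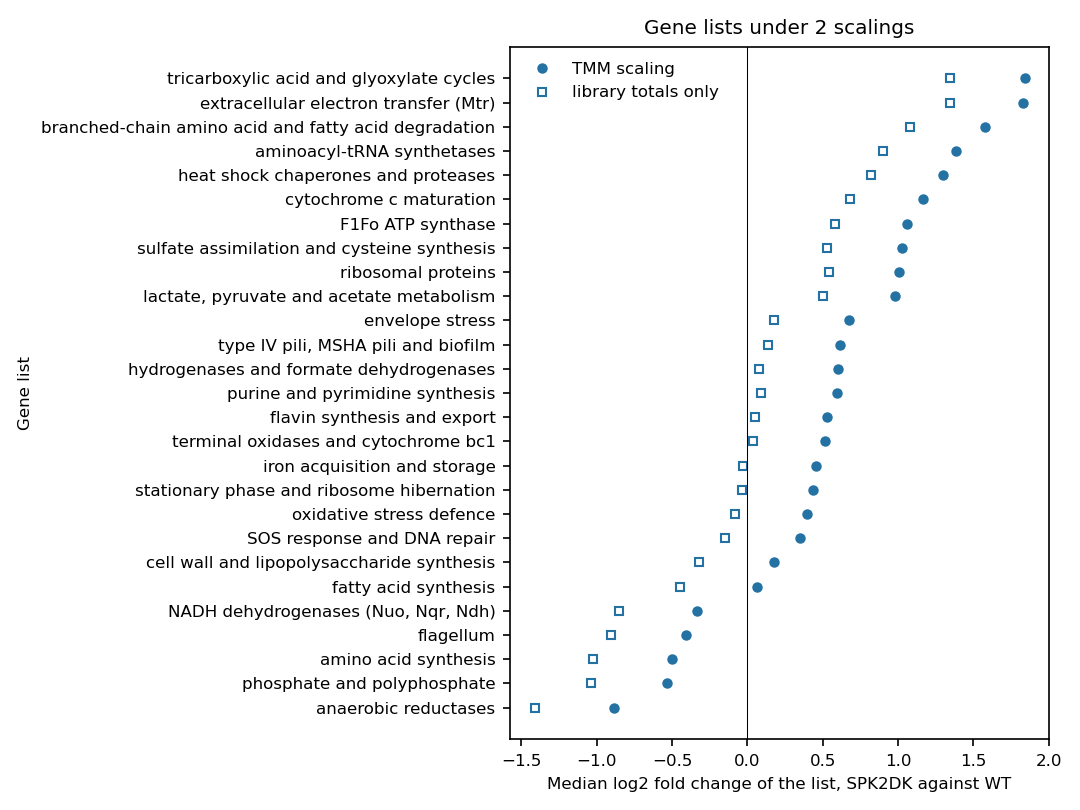
Median log2 fold change (x axis, SPK2DK against WT) of each of the 27 tested gene lists (y axis), with TMM factors (filled circles) and with library totals only (open squares). Library totals moved every list to the left, and the medians of iron acquisition, stationary phase, oxidative stress, SOS response, cell wall and fatty acid synthesis genes changed sign, while that of the tricarboxylic acid list, 1.84 with TMM, stayed above 0.

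Set directly against SCFP1, SPK2DK had higher transcripts of all 16 listed genes of hydrogen and formate metabolism. Higher too were 7 of 10 listed genes of electron transfer and all 7 of ATP synthase. Lower were all 9 listed phosphate genes and 10 of 15 DNA repair genes. In these lists 1 electron transfer gene fell and 2 repair genes rose. With the preset correlation camera called these lists, and with an estimated one 0 of them (adjusted p = 0.158 to adjusted p = 0.427 with an estimated correlation). This contrast does not tell which strain differs from WT. In SPK2DK against WT 9 of the 15 repair genes rose and 1 fell. Of the 16 hydrogen and formate genes 8 rose and 6 fell there, and of 15 NADH dehydrogenase genes 3 rose and 6 fell. Camera did not call these lists against WT (adjusted p = 0.0767, 0.197 and 0.334), though without WT replicate 2 it called the repair list (0.0452). The 4-hydroxyphenylpyruvate dioxygenase gene hppD was at 18.4 ± 2.25 CPM (SD, n = 3) in SCFP1 and 3078 ± 115 CPM (SD, n = 3) in SPK2DK, a log2 fold change of 7.39 ± 0.22 (SE). The gene queC, of queuosine synthesis, was at 796 ± 30.1 CPM (SD, n = 3) in SCFP1 and 54.5 ± 7.51 CPM (SD, n = 3) in SPK2DK (-3.87 ± 0.13). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1780 genes were higher and 1641 lower in SPK2DK, and 1026 and 823 of them by at least 2-fold (561 and 1568 with library totals). The strains did not overlap for 86.0% of genes, against 10% by chance. With library totals only, 1029 were higher and 2438 lower (29.7% higher, against 52.0%), and the median of all genes moved from 0.035 to -0.57.

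Among only the genes with a symbol, the next largest rises in SPK2DK over SCFP1 were ompW (6.89 ± 0.18, SE), rmf (6.80 ± 0.25), yiaY (6.67 ± 0.23) and exaC (6.44 ± 0.14), and the next largest falls pstC (-3.44 ± 0.21), msrA (-3.37 ± 0.17), pstA (SO_RS19890) (-3.27 ± 0.18) and mgtE (SO_RS05280) (-3.18 ± 0.26). All 16 genes of hydrogenases and formate dehydrogenases rose, also 16 adjusted over the list alone, led by fdnG (5.03 ± 0.12), fdhE (4.93 ± 0.15) and hypB (4.19 ± 0.14). Together these genes had adjusted p = 3.7e-05 and adjusted p = 0.345 with an estimated correlation. All 11 tricarboxylic acid cycle genes rose, also 11 adjusted over the list alone, led by sucD (4.20 ± 0.11). Camera gave adjusted p = 0.00031 and adjusted p = 0.427 with an estimated correlation. All 7 ATP synthase genes rose, also 7 adjusted over the list alone, led by atpE (2.44 ± 0.16) and atpA (2.37 ± 0.16). For this list camera gave adjusted p = 0.00587 and adjusted p = 0.427 with an estimated correlation. Of 18 heat shock genes, 15 rose and 2 fell, the same counts adjusted over the list alone, led by dnaK (5.09 ± 0.20), htpG (3.64 ± 0.12) and dnaJ (3.31 ± 0.14). Its camera test gave adjusted p = 0.00086 and adjusted p = 0.427 with an estimated correlation.

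All 9 phosphate and polyphosphate genes were lower in SPK2DK than in SCFP1, also 9 adjusted over the list alone. The list test gave adjusted p = 0.00054 and adjusted p = 0.158 with an estimated correlation. Of 15 SOS and DNA repair genes, 10 fell and 2 rose, the same counts adjusted over the list alone, led by recN (-2.95 ± 0.10, SE), ruvC (-2.18 ± 0.15) and recO (-2.11 ± 0.13). The members as a set had adjusted p = 0.0188 and adjusted p = 0.345 with an estimated correlation, and the call was also lost with limma on log2(FPKM + 0.1). Of 15 NADH dehydrogenase genes, 12 rose, also 12 adjusted over the list alone, led by nuoM (1.71 ± 0.17) and nuoN (1.70 ± 0.18). Together these genes had adjusted p = 0.00568 and adjusted p = 0.428 with an estimated correlation, and DESeq2 statistics did not call them. Of 54 ribosomal protein genes, 31 rose and 7 fell, the same counts adjusted over the list alone, and with library totals 21 rose and 22 fell. Its camera test gave adjusted p = 0.0300 and adjusted p = 0.785 with an estimated correlation. The call was also lost with library totals, DESeq2 statistics, limma on FPKM and without SPK2DK replicate 1 (adjusted p = 0.0603, with 0.0110 to 0.785 over the alternatives). Of 11 stationary-phase genes, 9 rose and 2 fell, the same counts adjusted over the list alone, led by rmf and hpf (SO_RS15955) (5.19 ± 0.19). Camera gave adjusted p = 0.0300 and adjusted p = 0.481 with an estimated correlation. Of the 10 electron transfer genes, 7 rose and 1 fell, the same counts adjusted over the list alone, led by cymA (4.44 ± 0.20), SO_1776 (4.33 ± 0.17) and mtrC (4.15 ± 0.18). For this list camera gave adjusted p = 0.00792 and adjusted p = 0.345 with an estimated correlation. The genes SO_1518 to SO_1522 rose by 2.71 ± 0.17, 2.35 ± 0.13, 1.08 ± 0.08, 2.37 ± 0.10 and 1.91 ± 0.12 on the log2 scale.

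Camera called 16 of 27 lists, 14 higher and 2 lower, and 0 with an estimated correlation, where 2 had an unadjusted p below 0.05. Fry, which tests whether members move 1 way without comparing them with other genes, called 25. DESeq2 statistics gave 10 lists. In fits to these 6 libraries alone camera called 16 lists for the strains and up to 15 for splits that mixed them. The median of the aminoacyl-tRNA synthetase list, of which 15 genes rose and 2 fell with TMM factors (15 and 2 adjusted over the list alone, adjusted p = 0.0158 and adjusted p = 0.458 with an estimated correlation), turned from 0.55 to -0.064 with library totals. Its call was lost with them, with DESeq2 statistics, with limma on FPKM and with the length trend removed.

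**Figure D2:**
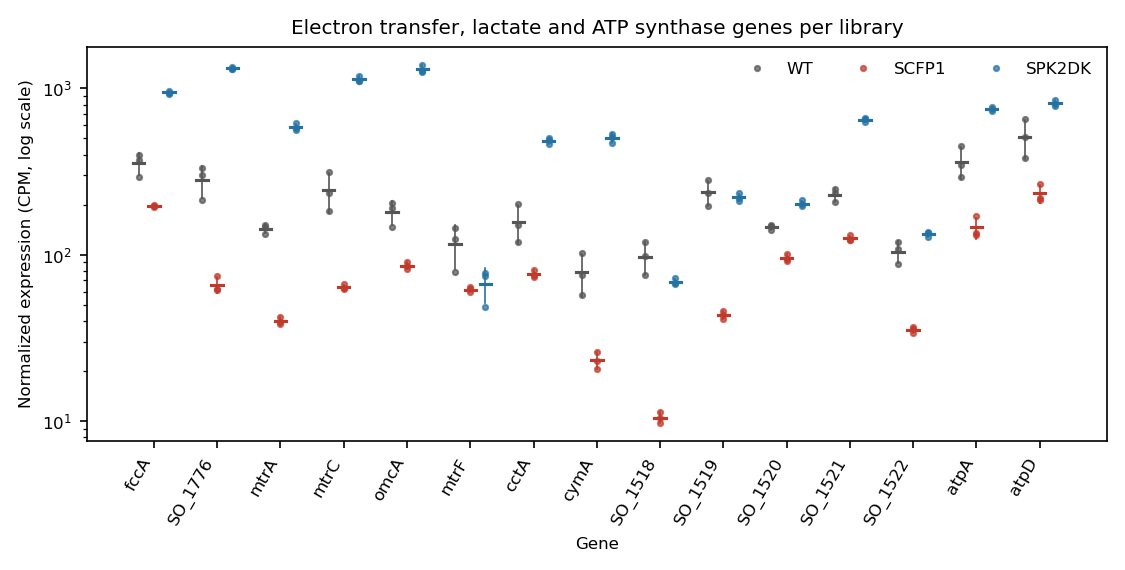
Normalized expression (y axis, CPM on a log scale) of genes of extracellular electron transfer, the lactate list and ATP synthase (x axis) in WT, SCFP1 and SPK2DK. Points are the 3 libraries of each strain, horizontal bars their means and vertical lines 1 SD to either side. The 3 SCFP1 values lie below those of WT for mtrC (means 63.9 and 244 CPM), whereas SPK2DK (1136 CPM) lies above.

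The labels place the engineered strains on opposite sides of WT, so genes called in both comparisons against WT were counted by direction. In both strains 918 genes were higher, where independent lists of these sizes would share 617, and 1047 were lower, against 689. Among the genes higher in both were nadS (SO_RS22440), nadS (SO_RS22830), the primase gene dnaG (log2 fold changes 2.74 ± 0.10 and 2.81 ± 0.10, SE, in SCFP1 and SPK2DK) and the outer membrane assembly gene bamA (2.51 ± 0.13 and 2.99 ± 0.13). Among those lower in both were fliE (-2.42 ± 0.23 and -2.48 ± 0.24), flgF (-2.32 ± 0.15 and -2.47 ± 0.15) and flgJ (-1.97 ± 0.16 in each), with rrf (SO_RS19495) at 1, 0 and 1 counts in SCFP1 and at the WT and SPK2DK counts given above. Another 368 genes were lower in SCFP1 and higher in SPK2DK, against 628 for independent lists, among them hppD (-4.78 ± 0.20 and 2.61 ± 0.17), yiaY (-4.02 ± 0.20 and 2.65 ± 0.19), prpF (-2.56 ± 0.15 and 2.23 ± 0.14) and dnaK (-2.22 ± 0.18 and 2.87 ± 0.18). The reverse held for 333 genes, against 677, among them msrA (2.28 ± 0.16 and -1.09 ± 0.17), mgtE (SO_RS05280) (2.01 ± 0.24 and -1.18 ± 0.26), pstA (SO_RS19890) (1.37 ± 0.16 and -1.91 ± 0.19) and rrtA (1.26 ± 0.18 and -1.29 ± 0.21).

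In total 1965 genes changed the same way and 701 opposite ways. These numbers depended on the scaling: with library totals 617 genes were higher in both (395 for independent lists), 1219 lower in both (961), 194 lower in SCFP1 and higher in SPK2DK (344), and 765 the reverse (1105). In 20 simulations of unchanged strains sharing the WT libraries, both numbers were 0. Unchanged strains give few or no calls, so this does not show how much of the overlap comes from the shared libraries. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.373 and 66.2% had the same sign. In the simulation r was 0.498 and the share 66.7%, values that equal groups sharing a control give whatever their spread. They therefore do not show how much of the shared direction comes from the WT libraries. The covariance keeps the size of the changes. It was 0.586, against 0.0143 simulated with a spread pooled over the strains, a difference of 0.571. The simulation holds only the spread between replicates, while WT replicates were the least alike and the strains did differ. It therefore does not show how much of the covariance comes from the WT libraries. The 2 sets of calls share these libraries, so the numbers for independent lists are no reference for this either. With 3 WT libraries the controls could not be split into parts of at least 2, and part of the shared direction may come from them.

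**Figure D3:**
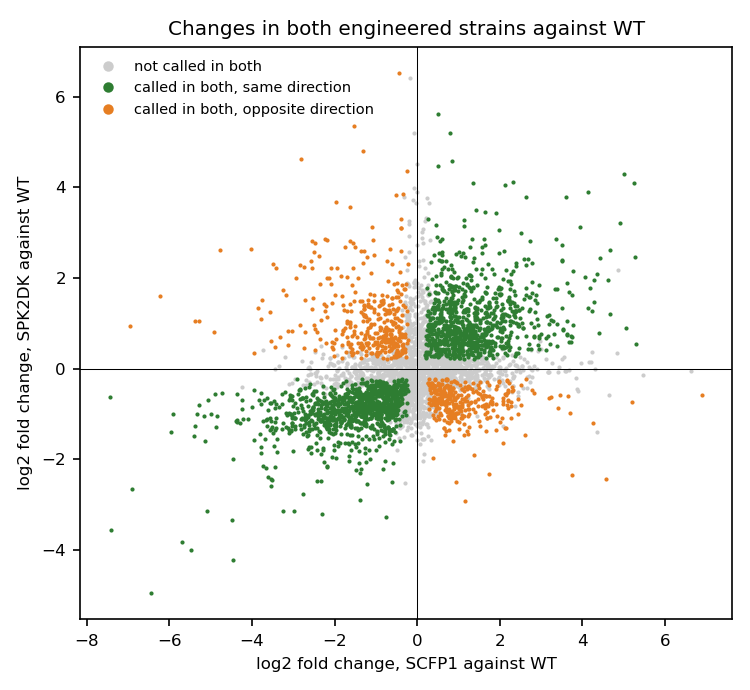
Log2 fold change of each tested gene in SCFP1 against WT (x axis) and in SPK2DK against WT (y axis). Each point is a gene, coloured by whether it was called in both comparisons in the same direction (1965 genes), in opposite directions (701 genes) or not in both.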

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

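Removing the length trend, leaving out ssrA and rnpB and keeping 1 row per family of copies were chosen after seeing the data. Of the counts of genes and lists under the alternatives, 252 stayed within 1.5 times their value and 4 did not. With an estimated correlation 0 lists were called in SCFP1 against WT, 0 in SPK2DK against WT and 0 in SPK2DK against SCFP1, where DESeq2 statistics gave 10 lists against 16, and the cause was not tested. Leaving out single libraries gave 3329 to 3740 genes for SCFP1 against WT, 2904 to 3535 for SPK2DK against WT and 3179 to 3673 for SPK2DK against SCFP1, and 1724 to 2270 genes with the same and 587 to 792 with the opposite direction in both strains. Over all alternatives the number with the opposite direction reached 978. With 1 row per family 3496, 3169 and 3363 genes were called. In fits to only the 2 strains compared, which do not borrow the spread of the third, 3437, 2977 and 3765 were called. With all 9 libraries these were 3542, 3239 and 3421. The FPKM filter removed no gene, so its absence tested nothing.

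No list's camera direction reversed with a call, but with library totals the medians of 2 called lists changed sign, stationary phase in SPK2DK against WT (-0.036) and aminoacyl-tRNA synthetases in SPK2DK against SCFP1 (-0.064). For gene lists 1838 values were the same, 68 lost a call, 35 of them with the estimated correlation, and 38 gained one. Envelope stress in SCFP1 against WT gained one with DESeq2 statistics (camera adjusted p = 0.00297, and 0.0692 in the main fit). Amino acid synthesis in SPK2DK against WT gained one without WT replicate 3 (camera adjusted p = 0.0106, and 0.0542 in the main fit), among other settings. Of the named genes of SPK2DK against WT 3 reversed, where scaling by totals lowers all genes. With library totals the log2 fold changes were -0.47 for SO_1781, -0.032 for SO_1520 and -0.17 for SO_1522. With limma on log2(FPKM + 1), filtered or not, they were -0.43, -0.028 and -0.13, and on log2(FPKM + 0.1) -0.45, -0.028 and -0.13. For named genes 4595 values were the same, and 11 lost and 15 gained a call without turning sign. Another 12 values turned sign with a call before or after, all of them of these 3 genes.

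With the replicate number as a block, 3476, 3110 and 3352 genes were called. The numbers do not pair the samples: 2 of 9 pairs of libraries with the same number had a correlation of deviations over 0.1 (range -0.575 to 0.371), and 0 libraries correlated best with their own number in both other strains. Among pairs with different numbers 8 were over 0.1, the highest at 0.644 (WT replicate 3 and SPK2DK replicate 1). Whether libraries share a batch under other numbers was not tested. At this depth, spread and number of libraries, simulated 1.5-fold changes were recovered in 55.2% to 62.7% of genes, and depth alone was not varied.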

Other observations

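Of the tests below, those on gene length, on the share of the 10 most abundant genes, on the 10 genes with the largest gain in share, on megaplasmid copy number and the splits for the number of genes at an adjusted p below 0.05 were chosen after the result was seen. Several runs of neighbouring genes without a symbol, chosen after their values were seen, changed together. SO_1891 to SO_1898 rose in SPK2DK against WT by 4.06 to 6.53 on the log2 scale, with SO_1892 going from 153 ± 5.25 to 13060 ± 1110 CPM (SD, n = 3). SO_3030 to SO_3033, next to fhuF, had log2 fold changes of -3.64 to -5.07 in SCFP1 against WT, and SO_3585 and SO_3586 rose by 6.91 ± 0.17 and 5.30 ± 0.12 (SE).

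Genes of the megaplasmid took 3.27% ± 0.251 (SD, n = 3) of the counts in WT, 7.86% ± 0.211 in SCFP1 and 5.01% ± 0.215 in SPK2DK. Of 55 tested megaplasmid genes outside copy families, 45 rose and 9 fell in SCFP1 against WT, and 42 rose and 7 fell in SPK2DK. SO_A0058 rose by 4.63 ± 0.18 (SE) in SCFP1, while SO_A0177 had a log2 fold change of -6.96 ± 0.27 and SO_A0178 of -6.23 ± 0.22.

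The larger megaplasmid share in SCFP1 could come from reads shared between near-identical copies, but with every copy family found left out the ratio of the shares, SCFP1 to WT, was 3.64. The totals include ssrA and rnpB, which took 18.9% and 9.48% of the counts in WT and 2.66% and 1.74% in SCFP1. Part of the larger share therefore comes from their fall. With TMM factors the median log2 fold change of the megaplasmid genes outside copy families was 2.37. A higher copy number as the only cause would move all megaplasmid genes alike. Yet 12.7% of those outside copy families were lower by at least 2-fold, and the quartiles of their log2 fold changes were 0.77 and 3.91. A copy number change together with regulation of single genes stays open, as does an effect of strain construction, and neither was tested.

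In SCFP1 the abundant small RNAs ssrA and rnpB and the short genes rmf, cspD and cydX were lower, with a median log2 fold change of -4.92. The coding genes were taken from the largest falls of this comparison, and ssrA and rnpB were chosen after their values were seen. That the 5 genes were all lower therefore follows from the choice. With the gene length trend removed, which moved genes by at most 0.624, the median of the 5 genes was -5.00. The other 531 protein-coding genes of at most 355 bases had a median of -0.11, with 199 higher and 220 lower. A general loss of short coding transcripts would thus not give the falls of rmf, cspD and cydX. For ssrA and rnpB, which are not protein-coding, a loss of such RNAs was not tested. The share of tRNA genes was 0.281% in WT and 0.607% in SCFP1, and that of rRNA genes 0.0318% and 0.0149%. A few genes taking most of the counts in SCFP1 could lower all others, but the 10 most abundant genes of a library took 8.58% ± 0.407 (SD, n = 3) there. A difference between cultures in growth stage or in IPTG may also give such falls, but it goes with the strain here and was not tested.

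The median of all genes in SPK2DK against WT was -0.57 when scaled by library totals. A few genes taking most of the counts could give such a shift. The 10 genes whose share rose most from WT to SPK2DK, however, each took at most 1.57% of the SPK2DK counts. Leaving out genes with such shares can move the median only a little, and without them it was -0.45. Counting reads at every copy could also give such a shift, but with 1 row per family the median was -0.62, though copies that were not joined may remain. A broader change in which genes are abundant, in the strain or its cultures, stays open and was not tested.

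Each pair of strains allows 10 splits of its 6 libraries, too few for a share under 0.05. In fits to those libraries alone, the number of genes was 3437 for SCFP1 against WT, 2977 for SPK2DK against WT and 3765 for SPK2DK against SCFP1, with 1 split as large (the real one) and a highest other of 0 by edgeR in each, where at most 4, 88 and 20 genes of other splits had an unadjusted p below 0.05. At 2-fold it was 2030, 1256 and 1845, again with 1 split as large and a highest other of 0. Splits that mix strains put the strain difference into the spread within groups, which leaves few or no genes to call. The 0 of the other splits was therefore to be foreseen and says little about chance. For gene lists the real split gave 5, 13 and 16 lists and the highest other 13, 17 and 15, with 10, 2 and 1 splits as large, and splits that mix strains still hold part of the strain difference. For the overlap, 100 splits of all 9 libraries were drawn, the real one included. As many genes with opposite directions came from 1 split, the real one (701, highest other 0), and as many with the same direction from 2 splits (1965, highest other 2046). The split with 2046 had the 3 SCFP1 libraries as its control. Only 2 other splits kept 1 strain whole as control, and 97 had a mixed control, so the splits say little about whether chance can be excluded.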
